A study of Candidatus Thioglobus autotrophicus with 6 samples.

How the data were processed

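RNA was measured in 6 libraries of Candidatus Thioglobus autotrophicus strain EF1, 2 from separate bottles at each of 3 oxygen levels: anoxic, low DO (about 3.8 µM initial dissolved oxygen) and high DO (about 22 µM). Per the labels' protocols, cells were collected on filters under nitrogen, a known amount of internal mRNA standards was added at extraction, DNA was digested in 2 separate steps, ribosomal RNA was depleted, and paired-end libraries were sequenced on an Illumina MiSeq. Per the labels, bottles were prepared in sets of 3, and 2 libraries per level were analysed here. Because the bottles were separate, p-values measure the spread between bottles carried through extraction and sequencing.

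The deposited counts were whole-number read counts per annotated gene of the EF1 chromosome, and per the submitters' processing notes FastQC, HISAT2 and DESeq2 were used. Versions, the counting tool, its treatment of strand and of reads with several matches, and the name of the genome build were not given in the sources used here. Gene positions are those in the authors' table, counted on its chromosome sequence. Of the gene lengths, 97.8% were multiples of 3, so most were taken as coding lengths. Among the exceptions was the abundant gene SP60_08185, with 344 bp. The table named 106 of 1637 genes by a symbol, and 2 symbols stood on 2 loci each. Per the file headers, the authors also deposited transcript copies (counts times a factor of copies per read for each library, 18228 and 18914 in anoxic, 25648 and 24138 in low DO and 16363 and 13982 in high DO) and transcripts per cell (copies divided by the number of cells). These relations held for every gene of the table. A last line of column sums without a gene name was left out. The authors' p-values per gene on transcripts per cell, and for each comparison their log2 fold changes with standard errors, mean normalized counts (a signal), Wald statistics (a score) and p-values from DESeq2, were used as deposited. Adjusted p-values that the authors' tables left missing, 164, 82 and 0 genes for low DO against anoxic, high DO against anoxic and high against low DO, stayed missing, and the last comparison was turned so that all fold changes are higher over lower oxygen.

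The following choices were made before the data were examined. Each pair of groups was compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 on the counts as deposited, with TMM scaling, the default expression filter (minimum count 10 and total 15) and 1 fit of all 6 libraries with group as the only term, which left 3 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. Of 21 fixed gene lists defined by patterns on symbols and products, the table allowed matching by symbol only: 13 held at least 1 gene and 5 held at least 4, and these were tested with camera of limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the lists of a comparison. None of these calls held with an estimated correlation. Genes named in the text are, per comparison, up to 8 largest increases and 8 largest decreases with a symbol among called genes with a mean of at least 20 counts and no overlap between groups, up to 4 members of each list by smallest p, the structural genes of nitrate, sulfur, carbon and nitrogen metabolism the table names, the 5 most abundant genes, and at most 2 locus tags that rose and 2 that fell. The rule asked for a known product, which the table lacks, so a symbol was taken in its place. Of the lists with fewer than 4 genes, results are given gene by gene where a member was called, and the lists of aminoacyl-tRNA synthetases (3 genes), DNA replication and cell division (2, gyrB and dnaK, the latter also among the chaperones) and the remaining citric acid cycle and secretion genes had no other called member on the deposited counts. After floor subtraction gyrB and 1 aminoacyl-tRNA synthetase gene were called higher in high DO than in the other groups.

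Further settings chosen at that time were DESeq2 1.42.0, DESeq2-type size factors, upper-quartile scaling, library totals alone, no filter, a filter of 50 counts in at least 2 libraries, only the 4 libraries compared, replicate number as a block, each library left out in turn, an adjusted p under 0.01 and, for lists, an estimated correlation. With a single library left in a group, that library is assumed to vary like the other groups.

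Settings added after the data had been seen were floor subtraction, scaling by the deposited copies per read and per cell, leaving out both libraries with the largest floor and, for the overlap, a different anoxic library as the control of each comparison. The floor of a gene was the highest of the minimum counts of all windows of 41 neighbouring genes that hold it (21 and 81 as further settings), per library, and was subtracted from the counts before the same fit. It lowered the biological coefficient of variation estimated by edgeR from 0.520 to 0.387 and left 1465 instead of 1636 genes to test. A gene whose own counts were 0 could not be told from one at the floor, and counts under the floor were not detectable.

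The fits were tested on simulated data with known folds in 10 repeats. In a first simulation, negative binomial counts were drawn with the spread of the deposited counts, and 200 genes were changed in low DO and, independently, 200 in high DO. Of 4-fold and 8-fold changes, 23.4% and 65.0% were recovered between high DO and anoxic cultures. In a second simulation, with the smaller spread of the floor-subtracted counts and 200 genes changed in high DO alone, the measured floors were added. Recovery was then 2.39% and 14.7% between high DO and anoxic cultures and 2.84% and 21.1% between high and low DO. After floor subtraction it was 46.6% and 78.1%, and 45.5% and 79.0%. In the second simulation nothing was changed between low DO and anoxic cultures. A median of 26.5 genes was called in that comparison (0 to 33), 26 of them higher in low DO. After subtraction 0 were called in all repeats. The added floors had been measured by the same rule that then subtracted them. Their removal was thus largely built in, for the recovery after subtraction as for the 0 calls. How well subtraction works on floors of another shape was not tested. Camera called a lowered ribosomal protein list in 10 of 10 repeats with the preset and in 4 and 2 of 10 with an estimated correlation (high DO against anoxic, and against low DO). Genes were drawn independently of each other there, so the preset was not tested on list members that move together.

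Total counts ranged from 256772 to 1128793, and 43 genes had 0 counts in high DO replicate 2. Replicates differed by more than sampling noise (chi-square per degree of freedom 44.0, 75.2 and 79.2 in anoxic, low DO and high DO), so no library was a copy of another. Scaling moved the median log2 fold change of all genes: with TMM it was 0.08, 0.14 and 0.20 for low DO against anoxic, high DO against anoxic and high against low DO, with library totals alone 0.61, -0.01 and -0.43, with DESeq2-type size factors -0.01, 0.29 and 0.43, with upper quartiles 0.33, 0.05 and -0.18, with copies per read 2.24, -0.13 and -2.02, and per cell 2.14, -0.09 and -2.01. Totals per cell were compared with exact permutation tests (two-sided) in SciPy 1.17.1 under Python 3.11.15, with tables handled in pandas 2.3.3 and numpy 2.4.6 and plots drawn in matplotlib 3.10.9.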

Results

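Gene expression was measured by RNA sequencing in strain EF1 of Candidatus Thioglobus autotrophicus, a cultured member of the SUP05 clade of marine sulfur-oxidizing bacteria that fixes carbon and can respire nitrate or oxygen. Pure cultures grew in sealed bottles of filtered seawater with thiosulfate as the energy source. The bottles were anoxic or received filtered air to an initial dissolved oxygen (DO) of about 3.8 µM (low DO) or 22 µM (high DO), with 2 libraries from separate bottles at each level. Total counts were 375879 and 363186 in the anoxic libraries (replicates 1 and 2), 543079 and 1128793 in the low DO libraries, and 532902 and 256772 in the high DO libraries. The comparisons asked how the transcriptome of this bacterium differed between the oxygen levels, taken in pairs.

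The most abundant gene on average, SP60_01315 (position 252935 to 253933 of the chromosome), took 7.68% of the counts as a mean of the 6 libraries, and between 1.90% (low DO replicate 2) and 18.6% (high DO replicate 2) in single libraries. The next 4 genes were SP60_08185 (1140310 to 1140653, mean 3.63%), SP60_03515 (648605 to 651514, 2.49%), SP60_00090 (13987 to 14247, 1.41%) and SP60_01865 (342025 to 343098, 1.21%). The order of these genes differed between libraries, with SP60_08185 above SP60_01315 in anoxic replicate 1 (13611 and 12204 counts). The files do not pair these identifiers with gene names. Together these 5 genes took 38.3% of the counts in high DO replicate 2 and 5.09% in low DO replicate 2.

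The libraries also differed in a count that all genes of a stretch shared. In low DO replicate 2 the 532 genes from 254404 to 738485 held a median of 578 counts (quartiles 557 and 594) more than in low DO replicate 1. This excess was nearly the same in long and short genes (ratio 0.995, for gene lengths that differed 4.74 times). In high DO replicate 1 the same genes held an excess of 320 counts (quartiles 282 and 365) over the scaled counts of high DO replicate 2. The floor of a gene, defined here as the highest of the minimum counts of all windows of 41 neighbouring genes that hold it, accounted in sum for 6.46% and 6.03% of all counts in the anoxic libraries, 21.1% and 56.9% in the low DO libraries and 42.5% and 6.86% in the high DO libraries. The end of the stretch above was set by the fall of the floor in high DO replicate 1. In low DO replicate 2 the floor stayed raised beyond it, with 498 counts at rplX (984087 to 984398). Its largest fall there, -314 counts, lay at 1219885 to 1221921. Across genes, rank correlations between libraries of one group were 0.596 to 0.902 on the deposited counts and 0.908 to 0.960 after the floor was subtracted (genes are not independent replicates). Those between groups also rose, from 0.362 to 0.892 before to 0.643 to 0.931 after, and the highest, anoxic replicate 2 with low DO replicate 1, exceeded that of the anoxic pair (0.908). The tests below used the counts as deposited, and values after floor subtraction, an alternative chosen after the data had been seen, are given beside some of them.

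**Figure D1:**
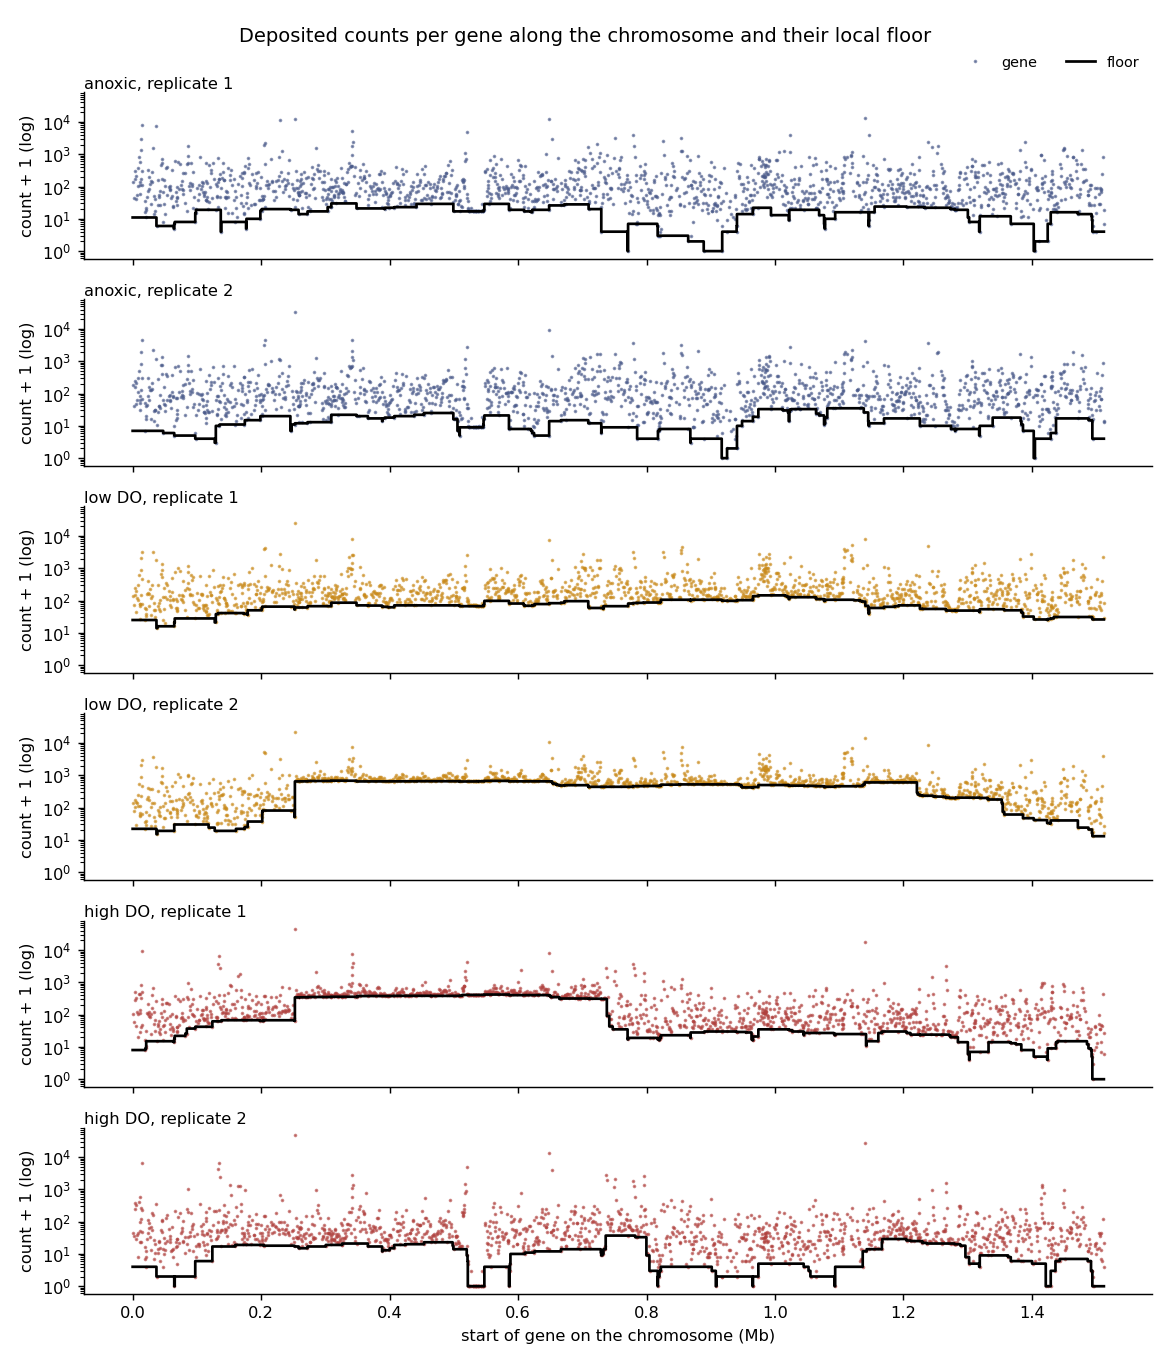
Deposited counts of each gene (points, count + 1 on a log axis) in each of the 6 libraries against the start of the gene on the chromosome in Mb, with the local floor over windows of 41 genes as a black line. The floor made up 56.9% of the counts in low DO replicate 2 and 42.5% in high DO replicate 1, against 6.03% to 21.1% in the other libraries.

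Between low DO and anoxic cultures, narZ was the only gene with a symbol that was called. This gene of the catalytic subunit of respiratory nitrate reductase (SP60_06775, 1254407 to 1258150), fell by 2.66 ± 0.73 on the log2 scale in low DO (SE, n = 2 libraries per group, edgeR adjusted p = 0.0445). Its TMM-scaled level went from 5533 ± 296 to 878 ± 525 CPM (mean ± SD). The iron-sulfur subunit narH (SP60_06780, 1258171 to 1259730) and the cytochrome b subunit narI (SP60_06790, 1260259 to 1260954) had log2 fold changes of -2.12 ± 0.61 and -2.12 ± 0.62 and were not called by edgeR (adjusted p = 0.0553 and 0.0573). All 3 genes had a lower CPM in both low DO libraries than in both anoxic ones. Scaled by copies per read, narZ, narH and narI were at -0.77, -0.16 and -0.06, and per cell at -0.69, -0.12 and -0.09, and none was called. These scaled values come from the deposited counts, floor included. In low DO replicate 2 the floor made up 218 of 375 counts of narH and 218 of 342 of narI. After floor subtraction all 3 genes passed when adjusted over their list alone, and none was called over all genes. Among genes without a name, SP60_00945 and SP60_00055 fell, with log2 fold changes of -3.63 and -3.34 (edgeR adjusted p = 0.0192 for each). They held 443 and 561 counts in anoxic replicate 1 but 96 and 63 in anoxic replicate 2, and were not called after floor subtraction.

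Of the fixed gene lists, the 4 genes of nitrogen oxide reduction were lower in low DO than the other genes (camera adjusted p = 0.0077, and adjusted p = 0.589 with an estimated correlation). Without low DO replicate 1 the list was not called (adjusted p = 0.119). One member, narZ, was called and 3 were not, and 3 passed when adjusted over the list alone. The remaining member, napH, an electron transfer component of periplasmic nitrate reductase, had a log2 fold change of 1.04 and no counts above the floor in either low DO library. None of the 18 ribosomal protein genes, the 9 genes of RNA polymerase and translation factors, the 4 chaperone and protease genes or the 4 heme synthesis genes was called by edgeR, and camera called none of these lists (adjusted p = 0.784, 0.536, 0.244 and 0.536). The ribosomal protein list had a median log2 fold change of 0.03 and a mean of 0.07, while camera placed it below the other genes. The sulfate adenylyltransferase gene sat, whose product acts in sulfur oxidation, the RuBisCO gene rbcL and the chaperone gene dnaK were not called, with log2 fold changes of -1.52, -1.60 and -2.61 (edgeR adjusted p = 0.317, 0.276 and 0.2). The signs of sat and rbcL turned to 0.36 and 0.44 with copies per read and to 0.45 and 0.46 per cell. The counts of dnaK were 11275 and 1112 in the anoxic and 2704 and 3165 in the low DO libraries, and its log2 fold change ranged from -3.48 to -0.10 over the other settings.

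In all, edgeR called 38 of 1636 genes between low DO and anoxic cultures, 27 higher and 11 lower in low DO, and 1 of the 106 genes with a symbol. An unadjusted p under 0.05 was found for 280 genes. Of the 27 higher genes, 23 had 10 or fewer counts above the floor in both low DO libraries. The floor made up a median of 100% of their counts there, against 42.9% and 78.1% for all genes in low DO replicates 1 and 2. After floor subtraction edgeR called 0 of 1465 genes (237 with an unadjusted p under 0.05) and DESeq2 called 75. The log2 fold change of narZ was then -1.77 ± 0.39 (adjusted p = 0.125), and 23 of the 38 genes no longer had enough counts to be tested. The ribosomal protein list and the list of RNA polymerase and translation factors were then higher in low DO (camera adjusted p = 0.000341 and 0.000894, with adjusted p = 0.435 for each with an estimated correlation). No member was called, with rplX at 2.08 and the elongation factor gene tuf (copy SP60_05230) at 2.59. Without anoxic replicate 1 or 2, edgeR called 3 genes (2 higher, 1 lower) and 18 (5 higher, 13 lower), and without high DO replicate 1 or 2, 79 (32 higher, 47 lower) and 165 (100 higher, 65 lower). With only the 4 libraries compared it called 95, 33 higher and 62 lower, so the excess of higher genes did not hold in every setting. Without low DO replicate 1 or 2 it called 0 (305 and 55 with an unadjusted p under 0.05). The call of narZ was lost in 15 of 20 other settings, among them the replicate block (adjusted p = 0.127), all 3 floor subtractions and both deposited scalings. Other losses among these were those without anoxic replicate 1 or 2 (adjusted p = 0.141 and 0.0705) and without low DO replicate 1 or 2 (0.165 and 1.0). Scaled by library totals alone, all 25 calls were higher, and scaled by the deposited copies per read or per cell, all 294 and 830 were higher in low DO.

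Between high DO and anoxic cultures, the nitrate reductase genes showed the largest decreases among genes with a symbol. The level of narZ fell by 4.99 ± 0.82 (SE, n = 2 libraries per group, edgeR adjusted p = 0.000276), from 1796 and 1979 counts in the anoxic libraries to 49 and 44 in the high DO libraries. Both narH and narI also fell (-3.93 ± 0.68 and -3.78 ± 0.69). After floor subtraction narZ was at -5.37, and narH and narI also fell. In the high DO libraries 0 and 7 counts of narH and 2 and 0 of narI lay above the floor, against 470 and 503 and 342 and 370 in the anoxic ones, so the sizes of their floor-subtracted changes were uncertain. The neighbouring gene SP60_06770 (1252606 to 1254219) fell (-4.62 ± 0.81), as did SP60_07580 (1398048 to 1398998, -4.66 ± 0.69). The list of nitrogen oxide reduction had 3 of 4 members lower (camera adjusted p = 5.2e-05, and adjusted p = 0.156 with an estimated correlation), and 3 passed when adjusted over the list alone. The remaining member napH was not called (0.76, and -0.27 without high DO replicate 2).

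The largest increases among genes with a symbol in high DO were iscA, for an iron-sulfur cluster assembly protein, and prpB and prpE, for methylisocitrate lyase and propionyl-CoA synthetase of the methylcitrate pathway of propionate metabolism. In high DO iscA (SP60_07660, 1415458 to 1415781) rose by 3.79 ± 0.84, prpB (SP60_00895, 168229 to 169104) by 3.42 ± 0.62 and prpE (SP60_00875, 161356 to 163224) by 3.31 ± 0.63 (edgeR adjusted p = 0.00351, 0.000571 and 0.000707). Counts of prpB were 52 and 48 in the anoxic and 587 and 340 in the high DO libraries. A run of 6 neighbouring genes from 161356 to 169796 that includes prpE and prpB rose with a median of 3.61. The counts of iscA were 189 and 23 in the anoxic and 816 and 1170 in the high DO libraries. Its log2 fold change was 6.01 without anoxic replicate 1, 2.95 without anoxic replicate 2 and 2.21 without high DO replicate 2. Its adjusted p was 0.0878 without anoxic replicate 2, 0.0778 without low DO replicate 1 and 0.0956 without low DO replicate 2. The succinate dehydrogenase gene sdhA and the protein translocase gene secD rose by 2.25 ± 0.73 and 1.79 ± 0.56 (adjusted p = 0.0408 and 0.0351), and these calls were lost in 10 and 11 of 20 other settings. After floor subtraction both were called, at 3.96 ± 0.49 and 1.95 ± 0.36 (adjusted p = 0.0030 and 0.0103). Among genes without a name, SP60_00730 and SP60_06840 rose by 6.55 and 6.06. The call of SP60_06840 held in all 20 other settings, while that of SP60_00730, with 176 and 9 counts in the anoxic libraries, was lost in 4 and its log2 fold change ranged from 5.41 to 9.93.

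Of the 18 ribosomal protein genes 6 fell from anoxic to high DO cultures and 12 were not called, and 10 passed when adjusted over the list alone (camera adjusted p = 6.7e-06, and adjusted p = 0.156 with an estimated correlation), with a median of -1.61 and 16 negative values. Examples were rplL (-3.08 ± 0.69), rpsR (-3.03 ± 0.62), rplI (-2.85 ± 0.61) and rpsJ (-2.79 ± 0.58), and after floor subtraction 11 of the 18 fell. Of the 9 genes of RNA polymerase and translation factors, rpoB for the beta subunit of RNA polymerase fell by 3.04 ± 0.76 and 8 were not called (camera adjusted p = 0.0329, and adjusted p = 0.156 with an estimated correlation). That list was not called without anoxic replicate 2 (adjusted p = 0.0824) or high DO replicate 2 (0.149), with copies per read (0.0532) or after floor subtraction over 21, 41 and 81 genes (0.715, 0.190 and 0.148). The call of rplL was lost without anoxic replicate 2 (adjusted p = 0.0559), and counts of rplL were 447 and 878 in the anoxic and 106 and 44 in the high DO libraries. Single genes of other lists also fell, among them sat (-2.63 ± 0.81, edgeR adjusted p = 0.0313) and the glutamine synthetase gene glnA (-2.38 ± 0.75, 0.0375). So did clpX for the ATPase subunit of the Clp protease (-1.95 ± 0.58, 0.0249) and the heme synthesis gene hemA (-1.73 ± 0.57, 0.0436). These calls were lost in 12, 13, 12 and 14 of 20 other settings, those of sat and glnA whenever any 1 library was left out. The lists of chaperones and proteases and of heme synthesis were not called (camera adjusted p = 0.23 and 0.641), and dnaK was not called at -2.88 ± 1.04. Its log2 fold change was -0.38 without anoxic replicate 1 and -4.67 without high DO replicate 2, and it was called in 3 of 20 other settings.

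In all, edgeR called 187 of 1636 genes between high DO and anoxic cultures, 59 higher and 128 lower in high DO, and 21 of the 106 genes with a symbol (5 higher, 16 lower). After floor subtraction it called 339 of 1465 genes, 130 higher and 209 lower, and 156 genes were called in both, all in the same direction. The share of lower calls was 68.4%, but 47.5% with DESeq2 (257 genes), 58.3% with DESeq2-type size factors, 79.6% with library totals alone and 83.7% per cell. Without anoxic replicate 1 or 2 it called 86 and 47 genes, without low DO replicate 1 or 2, 59 and 54, and without high DO replicate 2, 438, of which 271 were higher and 167 lower. Of the 21 genes named here as called, these settings lost 6, 11, 8, 9 and 3 in turn, and leaving out high DO replicate 1 lost 4. Scaling by copies per read lost 14 of the 21 and scaling per cell 7, with iscA, prpB and prpE lost on both scales and narH, narI, rplI, rpsJ and rpsR among those lost with copies per read. After floor subtraction the count was 188 without anoxic replicate 2, 225 without low DO replicate 2 and 150 without high DO replicate 2.

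**Figure D2:**
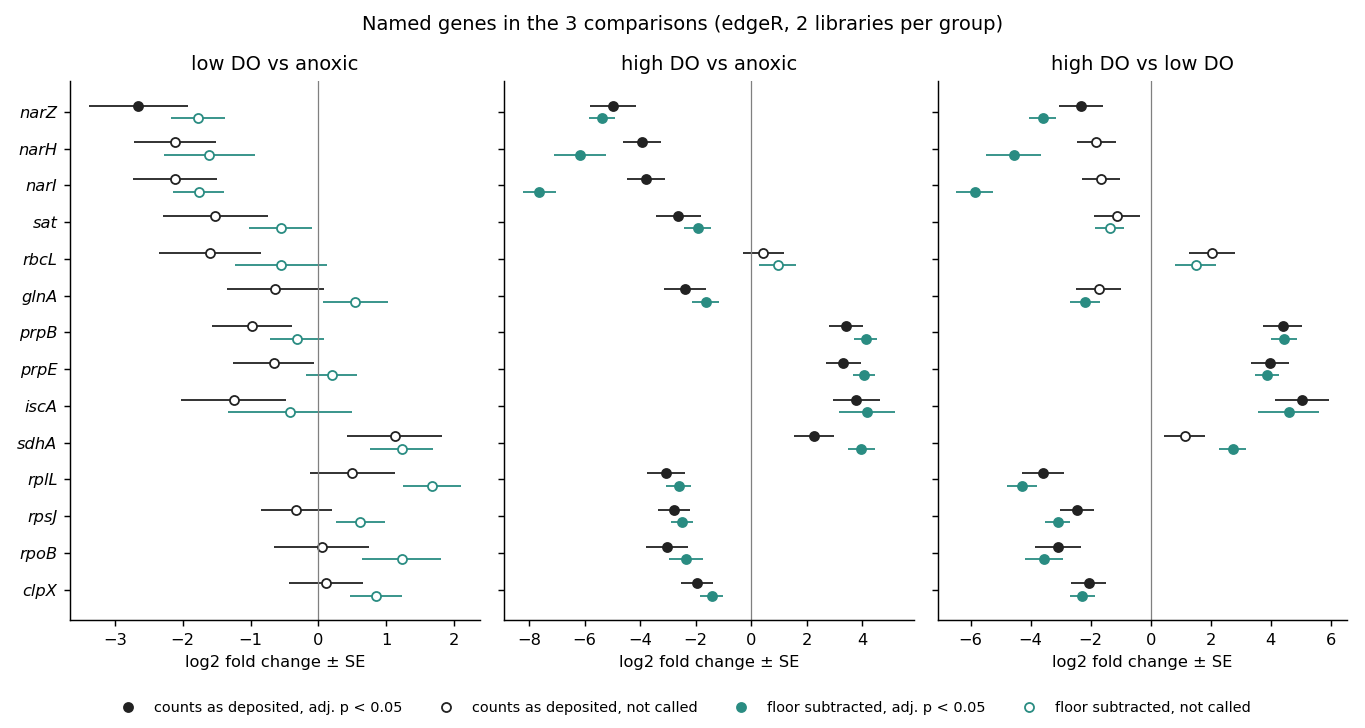
Log2 fold changes with their standard errors of 14 named genes in the 3 comparisons (panels), from the counts as deposited (black) and after floor subtraction (green), with 2 libraries per group. Filled points passed an adjusted p under 0.05, and narZ was at -4.99 and prpB at 3.42 between high DO and anoxic cultures.

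Between high and low DO, iscA, prpB and prpE were again the largest increases among genes with a symbol, and rplL, rpoB and nusA had the largest decreases. With more oxygen iscA rose by 5.04 ± 0.89, prpB by 4.39 ± 0.65 and prpE by 3.97 ± 0.65 (SE, n = 2 libraries per group, edgeR adjusted p = 0.000394, 4.6e-05 and 0.000184). None of these calls held with copies per read, and those of prpB and prpE were also lost per cell. The lowest log2 fold changes over the other settings were 2.17, 1.98 and 1.61. Counts of prpB were 69 and 77 in the low DO and 587 and 340 in the high DO libraries. The run of 6 genes that holds prpE and prpB rose with a median of 3.94, and 6 genes from 1412572 to 1416312 that include iscA rose with a median of 2.74. The coenzyme A synthesis gene panB rose by 2.44 ± 0.77, but it was not called after floor subtraction (2.66 ± 1.31, adjusted p = 0.16) or whenever any 1 library was left out. Among genes without a name, SP60_00730 and SP60_00830 rose by 7.80 and 6.73, and SP60_07585 and SP60_07580 fell (-4.59 and -4.21).

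Of the 18 ribosomal protein genes 8 fell from low to high DO and 10 were not called, and 10 passed when adjusted over the list alone (camera adjusted p = 1.4e-05, and adjusted p = 0.146 with an estimated correlation), with a median of -1.67. Among called members the largest decreases were rplL (-3.58 ± 0.70), rpmJ (-2.70 ± 0.82), rplW (-2.49 ± 0.64) and rpsJ (-2.47 ± 0.57), and after floor subtraction 16 of the 18 fell. Of the 9 genes of RNA polymerase and translation factors 4 fell (5 when adjusted over the list alone, camera adjusted p = 0.0103, and adjusted p = 0.146 with an estimated correlation). These were rpoB (-3.09 ± 0.76), nusA for a transcription elongation and termination factor (-2.85 ± 0.90), and both copies of tuf (SP60_05230, -2.63 ± 0.72, and SP60_05990, -2.60 ± 0.72). Values of the tuf copies are uncertain because reads of near-identical genes could have been split between them. A run of 20 genes from 977418 to 987161 that holds tuf, rpsJ, rplW and rplX fell with a median of -2.51. The levels of rplL, rpsJ and rpoB were lower in both high DO libraries than in all 4 others. The Clp gene clpX also fell by 2.07 ± 0.58. The quinone synthesis gene ubiA was called lower (-2.60 ± 0.79), but its 510 counts in low DO replicate 2 all lay at the floor, and after floor subtraction its log2 fold change was 2.09 ± 1.47 (adjusted p = 0.308).

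Of the nitrate reductase genes, narZ fell by 2.33 ± 0.74 from low to high DO (edgeR adjusted p = 0.0349), while narH and narI, at -1.81 ± 0.64 and -1.66 ± 0.65, were not called (adjusted p = 0.0585 and 0.0903). The list of nitrogen oxide reduction was called with 1 of 4 members lower and 3 when adjusted over the list alone (camera adjusted p = 0.0292, and adjusted p = 0.421 with an estimated correlation). It was not called without anoxic replicate 2 (adjusted p = 0.0544), low DO replicate 1 (0.142) or high DO replicate 1 (0.573). The same held for the 4 libraries compared alone (0.0706), copies per read (0.052) and both libraries of largest floor left out (0.391). After floor subtraction narZ was at -3.60 ± 0.44, and narH and narI also fell, from 245 and 157 and from 140 and 124 counts above the floor in the low DO libraries to the few given above in high DO. On the deposited counts the call of narZ was lost in 6 of 20 other settings. It was lost without low DO replicate 1 or 2 and without high DO replicate 1, with log2 fold changes of -1.58, -2.87 and -1.73. The replicate block (edgeR adjusted p = 0.108), DESeq2-type size factors and leaving out both libraries of largest floor also lost it. The genes rbcL, gyrB for DNA gyrase and glnA were not called, at 2.03 ± 0.77, 1.96 ± 0.73 and -1.74 ± 0.74, and they were called in 2, 5 and 6 of 20 other settings. After floor subtraction gyrB (1.45 ± 0.45, adjusted p = 0.0423) was called higher and glnA (-2.18 ± 0.50, 0.0147) lower. On the scales of copies per read and per cell rbcL and gyrB were lower in high DO without being called. The lists of chaperones and proteases and of heme synthesis were not called (camera adjusted p = 0.981 for each), and the median (0.16) and mean (-0.05) of the former differed in sign.

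In all, edgeR called 197 of 1636 genes between high and low DO, 69 higher and 128 lower in high DO, and 21 of the 106 genes with a symbol (4 higher, 17 lower). After floor subtraction it called 468 of 1465, 190 higher and 278 lower, and 145 genes were called in both, all in the same direction. The share of lower calls was 65.0%, but 51.2% with DESeq2-type size factors, 78.5% with upper-quartile scaling, 90.1% with library totals alone, 99.3% per copies per read and 98.5% per cell. Scaling by copies per read lost 4 of the 20 genes named here as called, and scaling per cell lost 3. Without low DO replicate 1 or 2 edgeR called 0 genes (352 and 285 with an unadjusted p under 0.05) and each of the 20 genes named here as called was lost. After floor subtraction 229 and 173 genes were called without these libraries and 230 without high DO replicate 2. On the deposited counts edgeR called 118 genes without anoxic replicate 1 and 109 without high DO replicate 2. Leaving out anoxic replicate 1 or 2 lost 6 and 5 of the 20 named genes, and high DO replicate 1 or 2, 4 and 5.

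**Figure D3:**
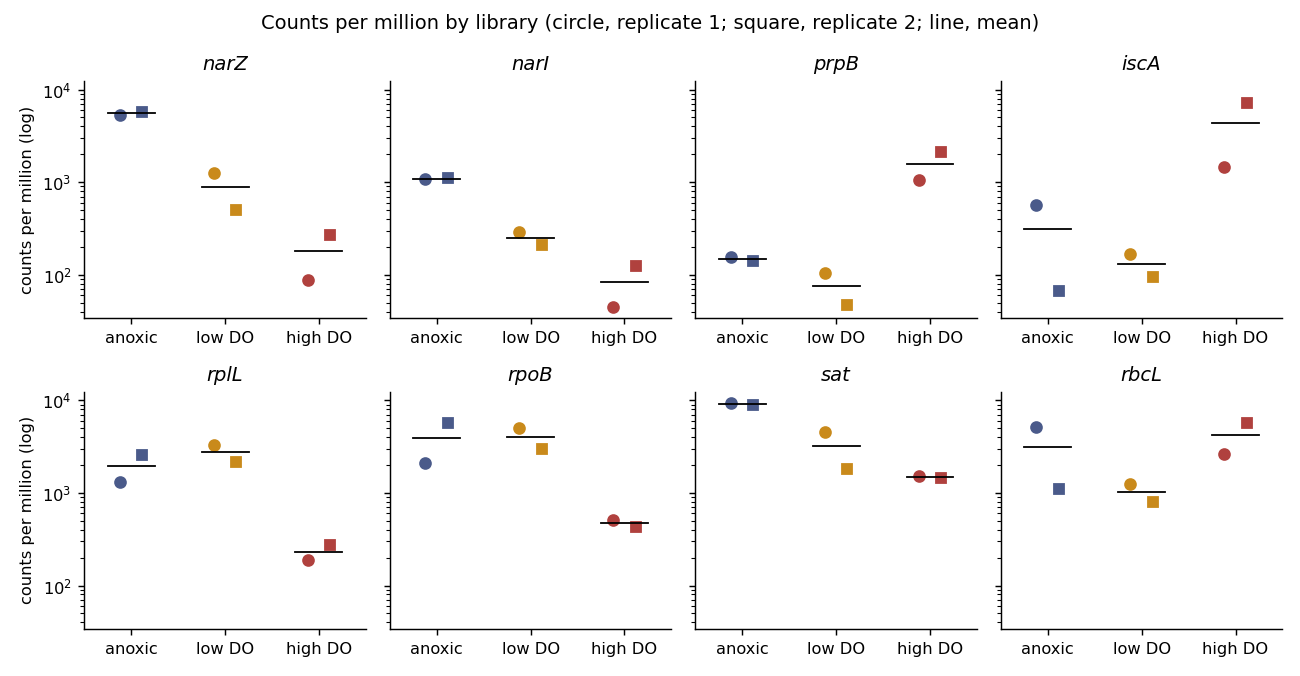
CPM (log axis, deposited counts scaled by TMM) of 8 named genes in each library of the anoxic, low DO and high DO groups. Circles are replicate 1, squares replicate 2 and lines the group means, and narZ lay at 5533 CPM in the anoxic and 179 in the high DO group as a mean of 2 libraries.

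Of the genes changed against the anoxic libraries, 10 were called in both low DO and high DO in the same direction, 6 higher and 4 lower, narZ among the latter, and 0 in opposite directions. Independent lists of these sizes would share 0.974 higher and 0.861 lower genes. These numbers ignore the floor, which was raised in low DO replicate 2 and high DO replicate 1. Of the 27 genes higher in low DO, 23 had 10 or fewer counts above the floor in both low DO libraries. The part of the floor in the overlap was not measured. With a different anoxic library as the control of each comparison, an alternative added later, the overlap was 0 genes, with 3 called in opposite directions, when anoxic replicate 1 was the control for low DO, and 1 gene the other way round. These fits called only 18 and 3 genes in low DO and 86 and 47 in high DO, so the part of the overlap that came from shared controls stays open. In 50 simulations of unchanged groups a mean of 0 genes in low DO and 0.02 in high DO was called, too few to measure that part either. Without each library in turn the overlap was 2 and 5 (anoxic replicates 1 and 2), 0 and 0 (low DO) and 20 and 91 (high DO). After floor subtraction edgeR called no gene in low DO and the overlap was 0.

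The authors' deposited tables of the same comparisons, made with DESeq2, called 205 genes between low DO and anoxic cultures (117 higher, 88 lower), 301 between high DO and anoxic (142 higher, 159 lower) and 220 between high and low DO (93 higher, 127 lower). DESeq2 as run here on the deposited counts called 42 (30 higher, 12 lower), 257 and 229. The choice of tool alone thus did not give the authors' 205 genes, and the cause of that gap was not tested. Of the genes called here by edgeR, 30, 179 and 173 were also called in the authors' deposited tables, each in the same direction. For narZ the authors' deposited table gave a log2 fold change of -2.51 between low DO and anoxic cultures and -4.50 between high DO and anoxic.

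Transcripts per cell, which the authors computed from internal mRNA standards and cell numbers, summed to 12.3 ± 0.42 in anoxic, 35.5 ± 3.31 in low DO and 11.5 ± 2.10 in high DO cultures (mean ± SD, n = 2 each). The low DO mean was 2.88 times the anoxic one and the high DO mean 0.932 times, and with 2 libraries per group the smallest p an exact two-sided permutation test allows was 0.333 (exact p = 0.333 and 1.0). After floor subtraction the means were 11.6 ± 0.43, 21.2 ± 6.97 and 8.39 ± 1.31, with the 2 low DO libraries at 26.2 and 16.3. By the authors' deposited p-values on transcripts per cell, 320 genes differed at p under 0.05 between low DO and anoxic cultures, all 320 higher in low DO, 238 between high DO and anoxic (30 higher, 208 lower) and 373 between high and low DO (10 higher, 363 lower). Of all genes, called or not, 97.6%, 47.7% and 3.48% were higher per cell at the higher oxygen level in these comparisons. After Benjamini-Hochberg adjustment the smallest of these deposited p-values was 0.0999, 0.181 and 0.0436.

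**Figure D4:**
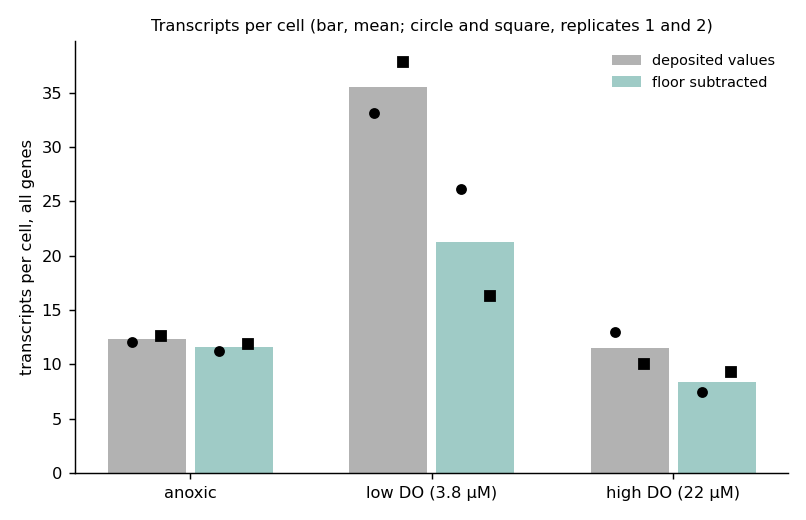
Transcripts per cell summed over all genes in the anoxic, low DO and high DO groups, as deposited (grey) and after floor subtraction (green). Bars are means of 2 libraries and symbols single libraries, and the low DO mean was 35.5 as deposited and 21.2 after floor subtraction.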

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

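The settings with subtraction of the floor, with the deposited factors, without both libraries of largest floor and with a different anoxic library for each comparison were chosen after the data had been seen, and all others before. Of 44 calls of genes named in the report, 10 kept their direction and call under every setting chosen beforehand with a value, and 18 under every later one. The calls of narZ, SP60_06770, SP60_06840 and SP60_07580 between high DO and anoxic cultures held under all 20 settings. Without low DO replicate 1 or 2, when 1 library stands for its group, each of the 20 named calls between high and low DO and each of the 3 between low DO and anoxic cultures was lost, and 8 and 9 of the 21 between high DO and anoxic. Counts of high DO replicate 2 were sparse (median 37 per gene), and the effect of depth was not tested. The table used here has no entries for the internal standards or for rRNA and tRNA, so those alternatives were not run.

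For low DO against anoxic (38 genes), the count was 25 with library totals alone, 95 (33 higher, 62 lower) with only the 4 libraries compared, 5 at an adjusted p under 0.01, 0, 0 and 0 by edgeR after floor subtraction over 21, 41 and 81 genes (196, 237 and 230 with an unadjusted p under 0.05, and 75 by DESeq2 over 41), 294 with copies per read, 830 per cell, and 0 (without low DO replicate 1 or 2, with 305 and 55 at an unadjusted p under 0.05) to 165 (without high DO replicate 2) with 1 library left out. For high DO against anoxic (187), it was 52 with only the 4 libraries compared, 77 at 0.01, 339 and 342 after floor subtraction over 41 and 81 genes, 31 with copies per read, 92 per cell, 324 without both libraries of largest floor, and 47 (without anoxic replicate 2) to 438 (without high DO replicate 2, 271 higher and 167 lower) with 1 library left out. For high against low DO (197), it was 64 at 0.01, 411, 468 and 467 after floor subtraction over 21, 41 and 81 genes, 574 with copies per read, 861 per cell, and 0 (without low DO replicate 1 or 2, with 352 and 285 at an unadjusted p under 0.05) to 248 (without high DO replicate 1) with 1 library left out. The cause was not tested for these shifts. Fits of 4 or 5 libraries have fewer residual degrees of freedom, but some of them called more genes than the main fit and others fewer.

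The labels do not say whether same-numbered bottles shared an inoculum, day or batch. Across genes, deviations of same-numbered libraries correlated at -0.17, 0.04 and -0.51 for low DO with anoxic, high DO with anoxic and high with low DO. After floor subtraction these correlations were -0.07, -0.08 and -0.06. They cannot show what the bottles shared. With the replicate number as a block, 29, 95 and 98 genes were called and 4 in both comparisons against anoxic.

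The number of lists called in low DO against anoxic, 1 (nitrogen oxide reduction), was 0 with the strict filter, which left that list too small to test, and 0 with an estimated correlation. It was 2 after floor subtraction over 21, 41 and 81 genes, where that list was again too small and the lists of ribosomal proteins and of RNA polymerase and translation factors were called instead. It was 0 (without low DO replicate 1) to 2 (without anoxic replicate 2) with 1 library left out. Of the 3 lists called in high DO against anoxic, 0 were called with an estimated correlation and 1 after floor subtraction over 21, 41 and 81 genes, since the 3 genes of nitrogen oxide reduction left were too few to test and the list of RNA polymerase and translation factors was no longer called (adjusted p = 0.190 over 41 genes). Of the 3 lists called in high against low DO, 0 were called with an estimated correlation. The overlap of 10 genes was 3 with library totals alone, 5 with the strict filter, 0 after floor subtraction over 21, 41 and 81 genes, 3 with copies per read, and 0 (without low DO replicate 1 or 2) to 91 (without high DO replicate 2). With a different anoxic library for each comparison it was 0 and 1. The overlap with the authors' calls in low DO against anoxic, 30 genes, was 0 after floor subtraction.

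Signs turned for rbcL (0.44 with copies per read and 0.46 per cell) and sat (0.36 and 0.45) in low DO against anoxic, for rbcL (-0.50 and -0.38) and gyrB (-0.81 and -0.58) in high against low DO, for ubiA in the same comparison after floor subtraction over 41 and 81 genes (2.09 and 1.10), and for napH in high DO against anoxic, which was -0.27 without high DO replicate 2 and 1.48 without high DO replicate 1. None of these values was called, and the cause was not tested.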

Other observations

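The tests of explanations in this part were all chosen after the patterns had been seen, on floor-subtracted counts where this is said. Some called genes were neighbours. Between high and low DO, 4 genes from 133644 to 136521 rose with a median of 5.34 on the log2 scale, and 4 genes from 1265734 to 1269377 rose with a median of 6.11 after floor subtraction. After floor subtraction 34 genes from 974402 to 992878, which hold tuf, rpsJ, rplW and rplX, fell with a median of -3.08. The nitrate reductase genes lay in a run of 8 genes from 1250557 to 1261323 that fell between anoxic and high DO cultures with a median of -5.29 after floor subtraction. The files do not pair most of these genes with names, and medians after floor subtraction include genes with almost no counts above the floor in 1 group, as narI in high DO (2 and 0), whose sizes were uncertain.

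Low DO replicate 2 and high DO replicate 1 carried 1 count shared by all genes of a long stretch. Genomic DNA left in the RNA is argued against by the ratio of extra counts in long over short genes, at most 1.01 in these libraries where lengths differed 4.74 times, and expression of the stretch by the spread of the extra counts, whose interquartile range was 6.45% and 26.1% of the median against 105% and 154% for the counts of the same genes in the other library of the group. Fragments with ends in distant abundant genes, counted in every gene between, stay open: 85.2% and 100% of the height of the floor's rises lay within 2 genes of the 10 most abundant genes (permutation p = 0.00244 and 0.0238 over 1636 circular shifts), mostly at SP60_01315 (595 and 277 counts). Of its falls, 13.8% and 0% did (permutation p = 0.0483 and 1.0), and the largest, -314 and -213 counts, lay at genes of abundance rank 301 and 35. These shares rest on few steps of at least 50 counts, 4 rises and 5 falls in low DO replicate 2 and 1 of each in high DO replicate 1. The largest rise lay at the same gene in both libraries. Libraries simulated with these floors, and no change between low DO and anoxic cultures, gave a median of 26 genes higher in low DO, beside the 27 called. Of these 27 genes, 23 had 10 or fewer counts above the floor in both low DO libraries. The simulation added those same measured floors, so the 2 numbers are not independent and their closeness was largely built in.

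Anoxic replicates 1 and 2 differed, with 11275 and 1112 counts of dnaK, against 2704 and 3165 in low DO and 405 and 689 in high DO. Of the 468 genes called between high and low DO after floor subtraction, 345 (73.7%) differed between the anoxic libraries in the same direction, replicate 1 lying toward high DO, against a mean of 48.9% and at most 66.9% over 1464 circular shifts (permutation p = 0.000683, one-sided). This is consistent with some oxygen reaching the cells of anoxic replicate 1, though dnaK in replicate 1 lay away from both oxygen groups, and another state that moves the same genes, or a shift of replicate 2 the other way, would give the same value. Oxygen at the low DO level during growth was examined with narZ, narH and narI. Their mean log2 ratio of replicate 1 to replicate 2 was -0.0232 (SD 0.0269 over these genes), against -1.72 for low DO over anoxic, both after floor subtraction. None of these genes was called over all genes in low DO after floor subtraction, while all 3 passed when adjusted over their list alone. Scaled by copies per read on the deposited counts, narH and narI were at -0.16 and -0.06. In low DO replicate 2 the floor made up 218 of 375 and 218 of 342 of those counts. Anoxic replicate 1 was thus not lower in these genes by the size seen in low DO after floor subtraction. That size was not called over all genes and changed with scaling, so the 3 genes cannot decide whether such oxygen was present. A difference in depth is argued against by a ratio of total counts of 1.03. No batch or date is given that would test the rest.

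The longest stretch of neighbouring genes with a median over libraries of at most 10 counts above the floor ran from 522010 to 547933. It held 34 genes, none with a symbol. Its counts above the floor were 205 in sum over the 6 libraries, against a median of 32401 in windows of as many genes elsewhere. This contrast follows from how the stretch was chosen. In high DO replicate 2, 31 genes of the stretch had 0 counts, against 12 of all other genes. Its medians of 644.5 counts in low DO replicate 2 and 406 in high DO replicate 1 equal the floor there. Near-identical copies whose reads were not counted are a candidate explanation. Of 17 gene lengths, 12 repeated in the same order 17 genes further on. The first was 807 bp, at 523305 to 524111 and again at 536138 to 536944. No window of 34 genes elsewhere repeated more than 3. Genes that were not transcribed in any culture would give the same 205 counts, so these explanations cannot be told apart without the sequence.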
